A study of Homo sapiens with 18 samples.

How the data were processed

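RNA was measured in 18 libraries of day-83 cerebral organoids from 2 human embryonic stem cell lines, H1 and H9, in 6 groups of 3 (vehicle, acute and chronic dopamine in each line), grouped per the labels. Libraries were poly(A) selected, strand-specific and paired-end, per the labels' protocols. The submitters' processing notes name the builds GRCh38 and hg38, which are names of the same assembly. The aligner, the counting tool and the annotation are not given in the sources used here.

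The authors deposited raw read counts per gene symbol for all libraries, 53853 entries, with no normalization per the file headers. The authors also deposited length-scaled abundances (TPM) for the same genes, used here only in an alternative test. The authors' 2 deposited comparison tables give a log2 fold change and an FDR-adjusted p-value per gene, made with a tool and samples that are not given in the sources used here. They also give a signed fold change, read here as a score whose sign gives the direction, per the file headers.

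Among the symbols with counts, 28 had been turned into dates, holding 0.439% of all counts, and were kept without a name. Genes were tested if they passed filterByExpr of edgeR 4.0.16 with the 6 groups, which left 17173 genes. Counts were scaled by TMM. An edgeR quasi-likelihood F test compared contrasts of the 6 group means in 1 fit of all libraries, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were acute and chronic dopamine against control and chronic against acute, as the mean over lines and within each line, the difference between lines of the acute and chronic effects, and H9 against H1. The standard error given with a log2 fold change is its size divided by the square root of the F statistic. Group means are TMM-normalised CPM, and library 9 was left out of the H1 control mean because of its depth, a choice made after the data were seen.

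Before the data were examined, 34 gene lists of dopamine signalling, activity, stress, metabolism and cell types were fixed, as were the tests, the alternatives named below as planned and the rule for naming genes. The 33 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. List tests within a line and for the line differences were added after the data were seen. Members were also adjusted over the list alone.

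The rule names, for acute and chronic dopamine averaged over lines, the 10 genes of largest change in each direction with the same sign in both lines and a mean log2 CPM of at least 0. If fewer than 5 pass, those of smallest p fill up to 5. Other comparisons name the 5 genes of smallest p in each direction, or 3 if none pass. Lists name up to 4 members of smallest p, and the authors' tables the 5 of largest fold. The receptor genes DRD1 to DRD5, FOS, NR4A1, HMOX1, NQO1, TXNIP, PPP1R1B and TH are always given. Genes of the sex chromosomes that tell sex, and genes without a symbol, are not named. Some genes that the rule selects are not reported here. FEZF2, EMX1, EOMES, SLC17A7, NKX2-1 and GAD1 as background of the lines, the blood and gut genes, and the collagen counts per library were chosen after their values were seen.

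The alternatives planned in advance were DESeq2 size factors and upper-quartile scaling, no low-count filter, a filter at 1 CPM in 3 libraries, a test against a fold of 1.2 (glmTreat), only the libraries compared, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma 3.58.1 on log2 TPM with a pseudocount of 1 or 0.1, an additive model, treatment alone, a threshold of 0.1, fry for lists, and leaving out each library. After the data were seen, the split of libraries by 10 blood and 6 gut genes was added as a covariate, as were fits of the 13 libraries with gut transcripts, of 12 of them without library 9, and without libraries 9 and 11. Work was done in R 4.3.3. Gene positions are from GENCODE release 44 on GRCh38, matched by symbol for 83 of 86 named genes.

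Each test was first run on simulated counts with the depths and means of the real libraries and 200 changed genes. For treatment comparisons averaged over lines the simulated change was the same in both lines. For chronic dopamine averaged over lines edgeR recovered 37.3% of the genes changed 1.5-fold, 85.1% of those changed 2-fold and 95.5% of those changed 4-fold, and called 9 unchanged genes among 16965. Other splits of the libraries were drawn 80 times with a fixed seed for comparisons over both lines, and all 10 splits of 3 against 3 were run within lines. An earlier, smaller draw that could repeat a split was replaced by distinct splits, and that changed the verdict for chronic against acute dopamine averaged over lines. Per-library levels of genes that tell sex were left out.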

Results

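The data are bulk RNA-seq of human cerebral organoids made with a ventral forebrain protocol from the embryonic stem cell lines H1 and H9. At day 83 organoids received vehicle (100 µM ascorbic acid, the control), 1 µM dopamine for 1 hour after a week of vehicle (acute), or daily 1 µM dopamine for 1 week and a final dose of 1 hour (chronic). Ascorbic acid was present at 100 µM in every group, the dopamine groups included. Dopamine is a catecholamine transmitter that oxidises readily, and the series title ties the response to reactive oxygen species. Each of the 6 groups holds 3 libraries, 18 in all, numbered 1 to 18 in the labels. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

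Total counts were 13647204 to 21691180 in 17 libraries. Library 9, an H1 control, held 43284, and 3 counts in it correspond to 69.3 CPM (counts scaled to library size), against 0.138 to 0.22 CPM in the others. The mean CPM of the H1 control group below therefore rests on libraries 7 and 8 (n = 2), and all other group means on n = 3, given as mean ± SD. The tests used all 18 libraries, and leading counts are also given without library 9.

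The libraries also differed in transcripts of blood and gut in a way that does not follow the groups. Libraries 4, 8, 13, 17 and 18 held 224 to 3211 counts of 10 blood genes, such as HBB (adult beta globin) and S100A9 (a neutrophil protein), and 1 to 10 counts of 6 gut genes. The other 13 libraries held 22 to 101 counts of the gut genes, such as CEACAM5 and FABP1, and 0 to 45 of the blood genes. These genes were chosen because they separate the libraries. No chronic library was among the 5 with blood transcripts. The gene counts of each comparison are therefore also given with this split as a covariate and within the 13 libraries with gut transcripts, where H9 control keeps only library 16 and H1 control libraries 7 and 9.

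**Figure D1:**
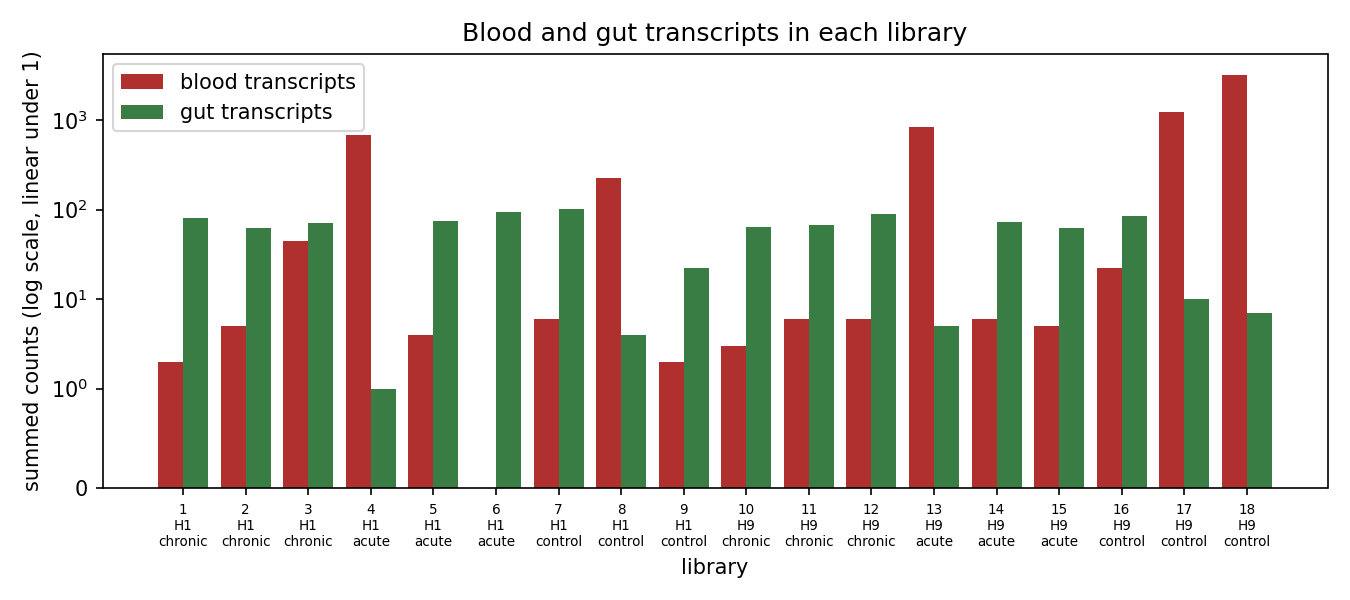
Summed counts of 10 blood genes and 6 gut genes in each of the 18 libraries, on an axis that is logarithmic above 1, with library number and group below each pair of bars. Libraries 4, 8, 13, 17 and 18 hold 224 to 3211 counts of the blood genes, and the other 13 hold at most 45.

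The organoids of the 2 lines differed in regional identity, which is the background of the treatment comparisons. H1 controls expressed genes of the dorsal forebrain and its glutamatergic neurons. FEZF2, a factor of deep-layer cortical neurons, was at 286 ± 69.1 CPM (n = 2), EMX1, a dorsal forebrain factor, at 125 ± 17, EOMES, a factor of cortical intermediate progenitors, at 124 ± 20.6, and SLC17A7, a vesicular glutamate transporter, at 236 ± 29. In H9 controls they were at 0.826 ± 0.365, 0.313 ± 0.318, 0.175 ± 0.0476 and 3.34 ± 0.708 CPM (n = 3). H9 controls held NKX2-1, a ventral forebrain and hypothalamic factor, at 52.7 ± 7.62 CPM against 0.0294 ± 0.0416 in H1, and GAD1, which makes the transmitter GABA, at 655 ± 98.9 against 6.95 ± 4.8.

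Averaged over treatments, 6278 of 17173 genes were higher and 5618 lower in H9 than in H1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 6784 and 6306 without library 9. The total was 11773 with the split as a covariate and 9228 within the libraries with gut transcripts. The smallest p-values among genes higher in H9 were those of ARHGAP36 (log2 fold change 10.14 ± 0.21 SE, adjusted p = 9.33e-18), SYT17 (4.11 ± 0.09), RET, a neurotrophic factor receptor (5.66 ± 0.13), TRIM58 (6.05 ± 0.14) and GCH1, which makes the cofactor of tyrosine hydroxylase (5.68 ± 0.13). Those lower in H9 were SLC17A7 (-5.95 ± 0.13), EMX1 (-9.71 ± 0.24), TFAP2C (-6.27 ± 0.16), FEZF2 (-8.02 ± 0.21) and EOMES (-8.98 ± 0.25). All 28 cell cycle genes were lower in H9, among them ASPM (-3.25 ± 0.12) and CCNB2 (-3.66 ± 0.15), and 28 passed adjusted over the list alone. The camera test with a preset correlation gave that list an adjusted p of 6.45e-18, but adjusted p = 0.444 with an estimated correlation, and no list passed with the latter in this comparison.

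The acute comparison asks what 1 hour of dopamine changes. Averaged over both lines, no gene passed in edgeR and none did in DESeq2, with 345 higher and 152 lower genes at an unadjusted p under 0.05. That 0 depends on the low-count filter, since edgeR without it called 51 higher and 23 lower, of which 72 are among the 17173 genes tested here. The genes of smallest p, none of which passed, had higher values for SLITRK6, a neuronal membrane protein (1.66 ± 0.27, adjusted p = 0.1), PDE5A (0.99 ± 0.19, 0.271), WLS, a carrier for Wnt secretion (0.89 ± 0.17, 0.271), OTX2 (1.1 ± 0.22, 0.271) and EBF1 (1.67 ± 0.34, 0.271). Values were lower for CAV1 (-1.4 ± 0.3, 0.372), CAV2 (-1 ± 0.22, 0.4), WNK4 (-1.13 ± 0.28, 0.81), C9orf16 (-2.97 ± 0.8, 0.899) and DBX2 (-2.37 ± 0.63, 0.924). C9orf16 held 583 of the 43284 counts of library 9. The count was 0 without library 9, with the split as a covariate and within the libraries with gut transcripts, 1 without library 4 and 4 without library 7.

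Genes of activity and of oxidative stress did not pass in the acute comparison averaged over lines. FOS and NR4A1, which neurons induce within an hour of activity, had log2 fold changes of -0.23 ± 0.15 and -0.16 ± 0.15 (adjusted p = 1 for both). Of 39 immediate early and activity genes 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.087). HMOX1 and NQO1, targets of the oxidative stress factor NRF2, had 0.08 ± 0.2 and -0.08 ± 0.14, and TXNIP, a regulator of thioredoxin, 0.25 ± 0.24. Of 28 NRF2 and antioxidant genes 0 passed over all genes and 0 adjusted over the list alone (0.487). Within lines the values went different ways. In H9 8 of 39 activity genes and 6 of 28 NRF2 genes had positive values. Camera gave adjusted p = 1.83e-05 and 0.000168 there, but 0.158 for both with an estimated correlation. In H1 25 and 21 had positive values (camera adjusted p = 0.562 and 0.181). In simulated data for this comparison edgeR recovered 53.7% of genes changed 1.5-fold and 73.1% of those changed 2-fold, and called 5 unchanged genes, over 16962 genes.

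Dopamine receptor and pathway genes differed in level between the lines, in both directions. In H9 controls DRD2 was at 22.3 ± 3.89 CPM, DRD1 at 3.7 ± 0.755, DRD5 at 3.98 ± 0.873 and TH, the rate-limiting enzyme of dopamine synthesis, at 16.4 ± 2.78. In H1 controls DRD2 was at 1.83 ± 0.841 CPM, DRD1 at 0.602 ± 0.395 and TH at 0.0588 ± 0.0831, and DRD5 had 0 counts in all 3 libraries, so fitted folds that include it in H1 depend on the prior count. DRD4 and PPP1R1B were higher in H1 controls, at 1.47 ± 0.25 and 31.3 ± 5.66 CPM against 0.174 ± 0.0436 and 0.741 ± 0.348 in H9. DRD3 was too low to test. The acute log2 fold changes were 0.33 ± 0.3 for DRD1, 0.16 ± 0.2 for DRD2, -0.84 ± 1.08 for DRD4, -0.34 ± 0.63 for TH and 0.37 ± 0.3 for PPP1R1B, a dopamine-regulated phosphatase inhibitor (adjusted p = 1 for each). TH was low in H1, and DRD4 and PPP1R1B were low in H9, so their averaged folds are uncertain. In H9 alone DRD5 had -0.05 ± 0.32. Of 19 dopamine receptor, synthesis and transport genes 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.459).

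The ventral forebrain and GABAergic list had the smallest p among the lists in the acute comparison. Of its 28 genes 26 had positive values (median log2 fold change 0.74), 0 passed over all genes, and 11 were higher adjusted over the list alone, among them EBF1, ERBB4 (1.01 ± 0.24), GAD1 (0.94 ± 0.27) and DLX2 (0.95 ± 0.29). The camera test gave an adjusted p of 1.41e-15, but adjusted p = 0.107 with an estimated correlation. With the estimated correlation 0 lists passed, against 11 with the preset one, 18 without library 16 and 7 without library 18. The positive values of the ventral forebrain and GABAergic list lay in H1, with a median of 1.54 and all 28 positive. In H9 its median was -0.06 and 9 were positive (camera adjusted p = 0.947). GAD1 was at 628 ± 139 CPM in H9 acute libraries and 655 ± 98.9 in H9 controls.

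Within H1, SLITRK6 (3.31 ± 0.47, adjusted p = 0.0134), WLS (1.74 ± 0.27, 0.0267) and PDE5A (1.75 ± 0.28, 0.0269) rose after acute dopamine, and no gene fell. SLITRK6 went from 0.306 ± 0.1 CPM (n = 2) to 3.16 ± 1.51 (n = 3), and WLS from 8.29 ± 0.164 to 27.4 ± 10.5. The count of 3 was 2 without library 9, 0 without library 8, 16 without library 4, 12 without library 7 and 5 without library 6. It was 5 with the split as a covariate, 0 within the libraries with gut transcripts and when only the compared libraries were fitted, 116 without a low-count filter, and 63 in DESeq2, where 50 were lower.

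Within H9 no gene passed after acute dopamine in edgeR, with 166 higher and 227 lower at an unadjusted p under 0.05, and DESeq2 called 2. Without a low-count filter edgeR called 61 higher and 56 lower, 90 of them among the genes tested here. The smallest p-values, none passing, were those of PAX5 (2.23 ± 0.39, adjusted p = 0.127), EBF3 (1.93 ± 0.35, 0.127) and TFPI2 (-2.96 ± 0.54, 0.127). Of 23 interferon response genes 4 were lower adjusted over the list alone, with IFITM3 at -1.24 ± 0.31 and B2M at -0.57 ± 0.15, and 0 over all genes (camera adjusted p = 9.53e-12, but adjusted p = 0.0563 with an estimated correlation). The blood transcript S100A9 had a lower value in the same comparison, 0.995 ± 1.59 CPM against 5.51 ± 4.77 in controls (adjusted p = 1), of which 17 and 18 hold blood transcripts, so a share of blood RNA in the lower interferon values is not separated here. There were 31 calls without library 16, 11 without library 13, 4 without library 14, 0 with the split as a covariate and 6 within the libraries with gut transcripts.

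The chronic comparison asks what a week of daily dopamine changes. Averaged over lines, genes of GABAergic neurons and of the ventral forebrain rose, a change that lies mostly in H1. GAD1 rose by 1.75 ± 0.28 on the log2 scale (adjusted p = 0.00418), GAD2, another GABA-making enzyme, by 1.55 ± 0.29 (0.0141), SLC32A1, the vesicular GABA transporter, by 1.64 ± 0.26 (0.00486), and TAC1, which encodes substance P, by 1.51 ± 0.22 (0.00277). The homeobox factors DLX1 (1.52 ± 0.3), DLX6 (1.6 ± 0.32) and NKX2-2 (2.15 ± 0.36) rose as well. NKX2-2 was low in H1, at 0.0857 ± 0.045 CPM in controls (n = 2) and 1.3 ± 0.405 in chronic libraries, so its averaged fold is uncertain. In H9 NKX2-2 was at 51.5 ± 5.42 and 70.7 ± 17. Of the 28 genes of the list 9 rose and 0 fell over all genes tested, and 19 rose and 2 fell adjusted over the list alone (median 1.19, camera adjusted p = 5.02e-29, and adjusted p = 0.00902 with an estimated correlation). It was the only list that passed with the estimated correlation. In H9 alone the list had a median of 0.07 with 0 genes higher past the threshold (camera adjusted p = 0.849), and TAC1 was at 94.8 ± 5.26 CPM in controls and 97.6 ± 18.9 in chronic libraries.

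In all, 64 genes rose and 10 fell among 17173, against 70 and 22 without library 9. ALK, a receptor tyrosine kinase (1.95 ± 0.3, adjusted p = 0.00378), DIO3, which inactivates thyroid hormone (1.72 ± 0.35, 0.0253), LINC01305 (1.64 ± 0.32, 0.0188) and CD27-AS1 (1.53 ± 0.19, 0.000953) rose. ALK and DIO3 were low in H1 controls, at 0.201 ± 0.132 and 0.203 ± 0.211 CPM (n = 2), so their averaged folds are uncertain. In H1 chronic libraries they were at 2.71 ± 0.658 and 1.85 ± 1.11. In H9 ALK was at 27.1 ± 2.75 CPM in controls and 30.5 ± 10.9 in chronic libraries, and DIO3 at 18.7 ± 1.48 and 21.9 ± 6.83. DMRTA2 (-1.92 ± 0.34, 0.0106), a transcription factor of early neural patterning, CAV1 (-1.72 ± 0.31, 0.0124), the kinase LYN (-1.38 ± 0.18, 0.000953), NEUROD1 (-1.22 ± 0.27, 0.0492), PLAT (-1.04 ± 0.22, 0.0419), HEG1 (-0.9 ± 0.18, 0.031), CRYM (-0.87 ± 0.18, 0.031) and NR4A2 (-0.84 ± 0.18, 0.047) fell. CD27-AS1 is an antisense gene, and how the authors' counting used strand is not given in the sources used here, so its value is uncertain. In GRCh38, GAD1 spans chromosome 2 from 170813213 to 170861151 and DLX1 the same chromosome from 172084740 to 172089677, both protein-coding genes.

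With the split as a covariate 19 genes rose and 2 fell, and within the 13 libraries with gut transcripts 1 rose and 2 fell. Without library 8 the count was 6, without library 11 it was 145, and without library 1, 12 or 17 it was 49, 47 and 42. An additive model of line and treatment called 0 genes, and edgeR without a low-count filter 386.

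Dorsal forebrain genes had lower values, with NEUROD1 alone passing over all genes, and 7 lower and 1 higher of 18 adjusted over the list alone, including NEUROG2 (-1.81 ± 0.47) and EMX1 (-2.07 ± 0.6). The list had a camera adjusted p of 1.31e-07, but adjusted p = 0.231 with an estimated correlation. EMX1 and NEUROG2 were low in H9, so their averaged folds are uncertain. EMX1 was at 0.313 ± 0.318 CPM in H9 controls and 0.023 ± 0.0398 in H9 chronic libraries, against 125 ± 17 and 74.7 ± 5.33 in H1. NEUROG2 was at 1.14 ± 1.05 and 0.112 ± 0.0392 in H9, and 160 ± 6.55 and 114 ± 7 in H1. NRF2 and antioxidant genes did not pass, with HMOX1 at 0.62 ± 0.2 (adjusted p = 0.247) and NQO1 at 0.36 ± 0.14 (0.398), 0 of 28 adjusted over the list alone and a camera adjusted p of 0.0684. TXNIP was at -0.16 ± 0.24, and FOS and NR4A1 both at 0.02 ± 0.15. Of 39 immediate early and activity genes 0 rose and 1 fell over all genes, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.543). In H1 2 of these genes rose and 0 fell over all genes (camera adjusted p = 0.445), and in H9 0 passed (camera adjusted p = 0.891). Of 24 cAMP and CREB target genes 1 rose and 1 fell over all genes (camera adjusted p = 0.291). DRD1 was at 0.54 ± 0.3, DRD2 at 0.38 ± 0.21, DRD4 at -0.8 ± 1.09, TH at 1.03 ± 0.48 and PPP1R1B at -0.85 ± 0.38, and none passed. TH was low in H1, and DRD4 and PPP1R1B were low in H9, so their averaged folds are uncertain. TH had 0.46 ± 0.22 in H9 and PPP1R1B -0.5 ± 0.33 in H1, where each is expressed, and neither passed there. In H9 alone DRD5 was at 0.53 ± 0.32.

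In H1, chronic dopamine libraries held more transcripts of GABAergic neurons and pigment cells. GAD1 rose from 6.95 ± 4.8 CPM (n = 2) to 58.2 ± 15.8 (n = 3), a log2 fold change of 3.09 ± 0.44 (adjusted p = 0.000907), and TAC1 (2.98 ± 0.41), ERBB4, a neuregulin receptor (2.66 ± 0.39), and SLC32A1 (2.7 ± 0.43) rose too. Of the 28 ventral forebrain and GABAergic genes 15 rose over all genes and 22 adjusted over the list alone (camera adjusted p = 1.4e-33, and adjusted p = 0.00789 with an estimated correlation). H1 acute libraries lay between, with GAD1 at 26.6 ± 10.4 CPM and DLX1 at 73.1 ± 37.6, where DLX1 was at 20.5 ± 17.5 in controls and 126 ± 36.3 in chronic libraries. Of 9 neural crest and melanocyte genes 5 rose, both over all genes and adjusted over the list alone, among them the pigment genes DCT (2.52 ± 0.34), TYRP1 (5.14 ± 0.71) and PMEL (3.11 ± 0.57) (camera adjusted p = 3.22e-10, and adjusted p = 0.0327 with an estimated correlation). TYRP1 had 0 to 4 counts in each control. Values of dorsal neuron genes were lower, with FEZF2 at 143 ± 13.2 CPM against 286 ± 69.1 in controls and SLC17A7 at 154 ± 11.3 against 236 ± 29. Of 18 dorsal forebrain genes 2 had positive values, 0 passed over all genes, and 4 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000255, but adjusted p = 0.416 with an estimated correlation).

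Among glial genes in H1, GJA1 (2.85 ± 0.34) and AQP4 (2.47 ± 0.55) rose, 2 of 14 astrocyte genes, and 5 adjusted over the list alone (camera adjusted p = 1.62e-05, but adjusted p = 0.129 with an estimated correlation). Of 8 oligodendrocyte lineage genes 3 rose, among them NKX2-2 and OLIG1 (2.79 ± 0.6), and 6 adjusted over the list alone (3.39e-06, but adjusted p = 0.0818 with an estimated correlation). Of 14 choroid plexus and ciliated genes OTX2 (2.04 ± 0.35) rose, and 10 adjusted over the list alone (5.32e-06, but adjusted p = 0.309 with an estimated correlation).

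In all, 229 genes rose and 15 fell in H1, and 229 and 51 without library 9. PDE5A (2.93 ± 0.29, adjusted p = 3.59e-05), SLITRK6 (4.46 ± 0.45), BTBD11 (2.92 ± 0.3), WLS (2.64 ± 0.28) and RXRG, a retinoid receptor (2.71 ± 0.3), had the smallest p among those that rose. SMIM11B (-1.51 ± 0.28), CRYM (-1.3 ± 0.24), KIAA0408 (-8.01 ± 1.57), CHRM5 (-2.01 ± 0.4) and ZNF860 (-1.57 ± 0.32) fell. SMIM11B has a near-identical copy that can share its reads, and KIAA0408 had 0 to 2 counts in the chronic libraries and 436, 0 and 1 in the controls, so both are uncertain. With the split as a covariate 165 rose and 8 fell, and within the libraries with gut transcripts 21 rose and 2 fell. The balance of directions depended on the method, with 153 higher and 106 lower in DESeq2, and 384 and 177 in edgeR without libraries 9 and 11. Without library 8 there were 46 calls, without library 1 there were 94, and without a low-count filter 535.

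In H9, chronic dopamine libraries held fewer transcripts of some midbrain and floor plate factors than controls, and fewer mesenchymal transcripts than controls 17 and 18. COL3A1, a fibrillar collagen, fell from 42.6 ± 37.5 to 0.223 ± 0.168 CPM (n = 3 each, -7.52 ± 1.31, adjusted p = 0.0125), and COL5A1 (-1.48 ± 0.24), COL6A3 (-4.92 ± 0.84) and COL1A2 (-5.62 ± 1) fell too. COL3A1 had 1146 and 1022 counts in H9 controls 17 and 18, which hold blood transcripts, and 10 in control 16, against 1 to 6 in the chronic libraries. COL1A2 and COL6A3 had 33 and 11 counts in control 16, near the 11 to 31 and 4 to 9 of the chronic libraries, while COL5A1 was at 10.6 CPM in control 16 and at most 6.37 in chronic libraries. Against controls, the fall of COL3A1, COL1A2 and COL6A3 thus rests on controls 17 and 18, and the list was not tested within H9 without both. The H9 acute libraries 13, 14 and 15 had 389, 924 and 151 COL3A1 counts, also above the chronic libraries. Of these acute libraries only 13 holds blood transcripts. Of 20 mesenchymal and matrix genes 8 fell over all genes, and 14 fell and 1 rose adjusted over the list alone (camera adjusted p = 5.68e-17, and adjusted p = 0.0434 with an estimated correlation). LMX1A, a floor plate and roof plate factor, fell from 24.7 ± 13.4 to 1.12 ± 0.555 CPM (-4.46 ± 0.63, 0.00445), with FOXA1 (-2.52 ± 0.45), EN1 (-3.62 ± 0.64) and EN2 (-2.93 ± 0.58), midbrain and floor plate factors. Of 19 midbrain, hindbrain and hypothalamic genes 4 fell, and 7 adjusted over the list alone (4e-07, and adjusted p = 0.0226 with an estimated correlation).

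In all, 3 genes rose and 96 fell in H9. Library 11 stood apart from the other H9 chronic libraries, with a chi-square per degree of freedom of 80.4 and 61.2 against 10 and 12, where 10 and 12 had 7.65. Without it 1 rose and 40 fell, and without libraries 9 and 11 it was 3 and 52. ARHGAP36 (0.75 ± 0.17, adjusted p = 0.0447) and OSTN (1.75 ± 0.39, 0.046) rose, and the remaining gene has no symbol. FREM1, a matrix protein (-2.64 ± 0.28, 0.000202), LYN (-2.36 ± 0.28), LMX1A, ITIH5 (-2.76 ± 0.4) and WNT5A, a Wnt ligand (-2.11 ± 0.31), had the smallest p among those that fell. With the split as a covariate 0 rose and 29 fell, and within the libraries with gut transcripts 0 rose and 7 fell. There were 59 calls in DESeq2 and 4 when only the compared libraries were fitted. Without library 12 or 17 there were 13 calls each, without library 16 there were 178, and without library 10 or 18 there were 44 and 48. Without a low-count filter there were 438.

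**Figure D2:**
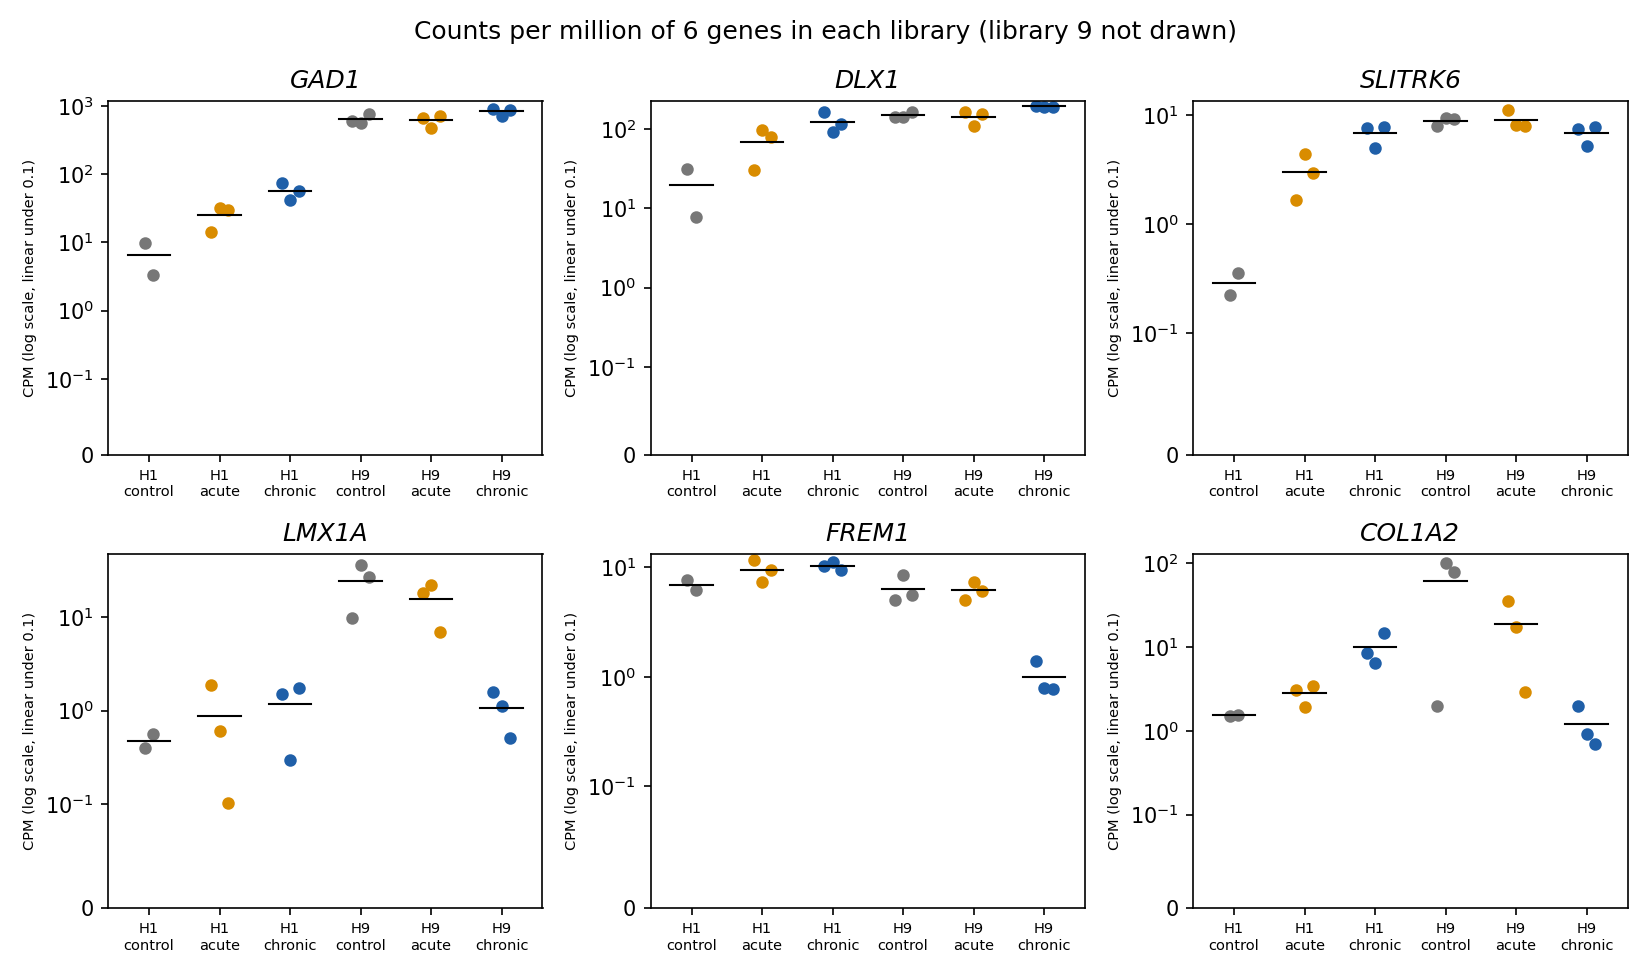
CPM of 6 genes in each library, 1 point per library and a line at the group mean, on axes that are logarithmic above 0.1, without library 9. GAD1 was highest in H9, and in H1 it was higher in chronic libraries than in controls. LMX1A was lowest in H9 chronic libraries among the H9 groups.

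The difference between the lines in their response was tested directly. For the chronic effect 11 genes had a larger log2 fold change in H9 and 292 a smaller one, and 33 and 270 without library 9. WLS (difference -3.22 ± 0.35, adjusted p = 0.000146), SLITRK6 (-4.81 ± 0.53), PDE5A (-3.39 ± 0.39), WNT5A (-4.21 ± 0.5) and BTBD11 (-2.88 ± 0.34) had the smallest p among those smaller in H9. OSTN (2.51 ± 0.49), SMIM11B (1.85 ± 0.37), ME3 (1.3 ± 0.3), KIAA0408 (7.93 ± 1.82) and CHRM5 (2.15 ± 0.52) were larger in H9. Of the 28 ventral forebrain and GABAergic genes 11 had a smaller change in H9, such as ERBB4 (-3.25 ± 0.48) and TAC1 (-2.94 ± 0.45), and 22 adjusted over the list alone (camera adjusted p = 8.26e-21, and adjusted p = 0.0373 with an estimated correlation). The count was 306 with the split as a covariate, 24 within the libraries with gut transcripts and 166 in DESeq2. The balance shifted to 118 larger and 441 smaller with 1 surrogate variable, and to 180 and 448 without libraries 9 and 11. The surrogate variable was -0.936 in library 9 and -0.098 to 0.129 in the others, so it mainly sets library 9 apart. Without library 8 it was 68, without library 1 it was 146, without library 17 it was 173 and without library 7 it was 194.

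For the acute effect no gene differed between lines in edgeR, with 138 and 500 at an unadjusted p under 0.05 in each direction, and DESeq2 called 1. Without a low-count filter edgeR called 30 and 65, 89 of them among the genes tested here. The smallest p-values, none passing, were those of SLITRK6 (-3.28 ± 0.54, adjusted p = 0.121), RXRG (-1.96 ± 0.37, 0.309) and WLS (-1.71 ± 0.34, 0.335). The count was 0 without library 9 and with the split as a covariate, 1 within the libraries with gut transcripts, 1 without library 7, 2 without library 4, 3 without library 13 and 4 without library 16.

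**Figure D3:**
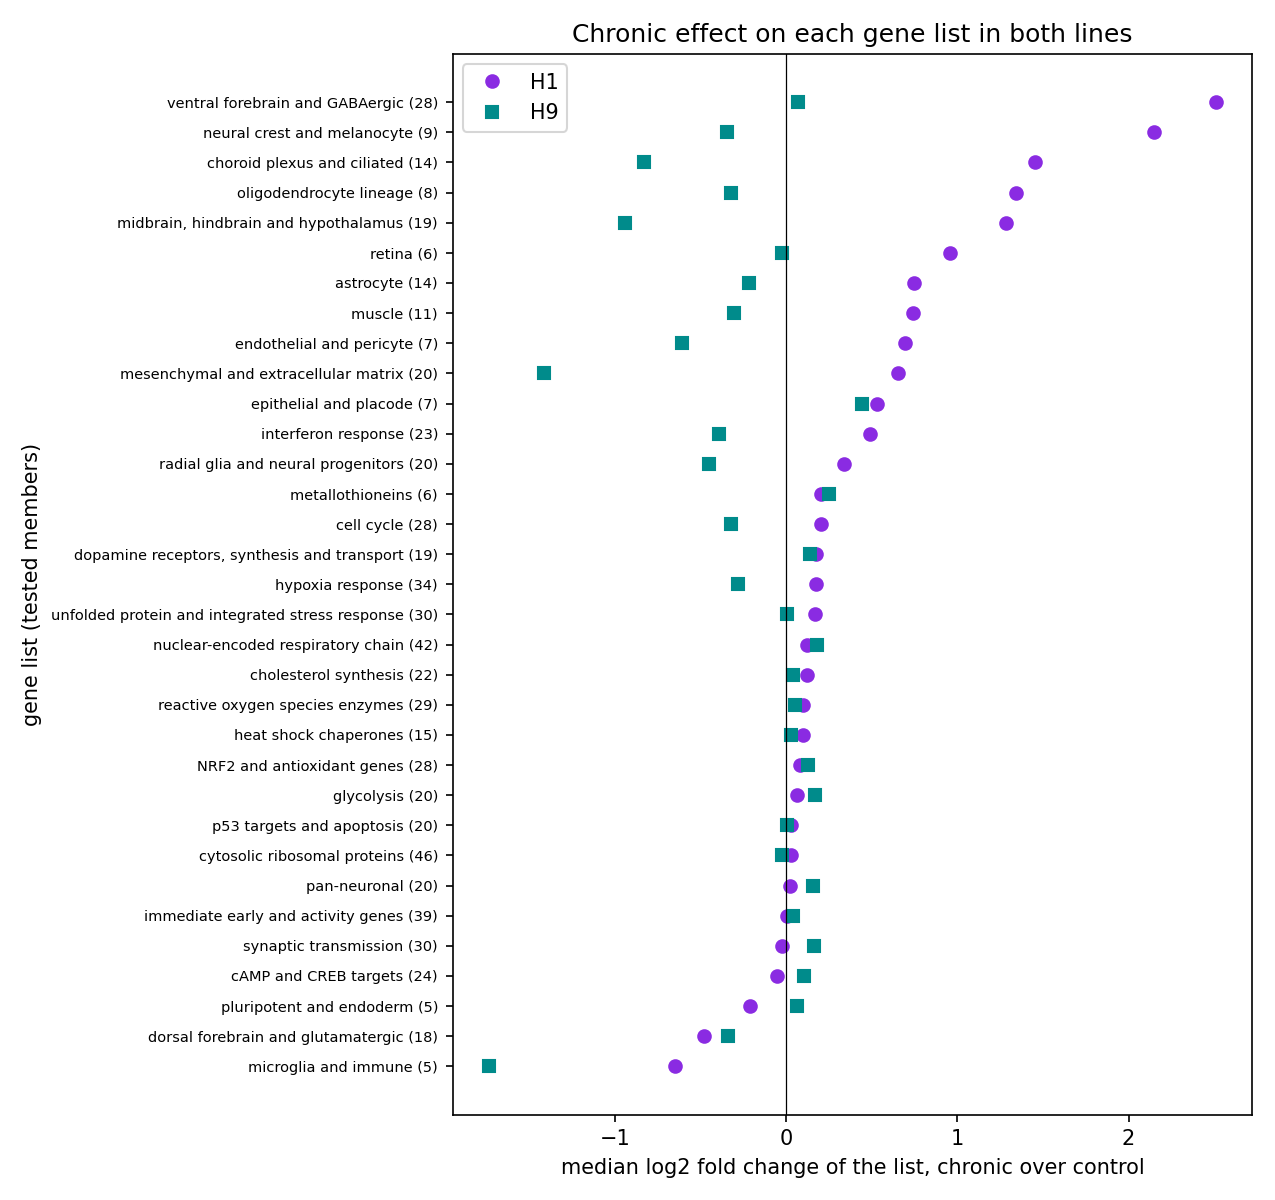
Median log2 fold change, chronic over control, of each gene list in H1 (circles) and H9 (squares), with the number of tested members in parentheses. The ventral forebrain and GABAergic list is at 2.51 in H1 and 0.07 in H9, and the mesenchymal list at 0.65 and -1.42.

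Chronic was also set against acute dopamine, a comparison without the controls. In H9 more genes fell than rose. FREM1 (-2.6 ± 0.28, adjusted p = 0.000265), PAX5 (-4.03 ± 0.46), EBF2 (-4.52 ± 0.53) and ZIC1 (-2.98 ± 0.37) were among those of smallest p, and ARHGAP36 (1 ± 0.17), HCRT, which encodes the neuropeptide orexin (1.79 ± 0.31), ME3 (0.97 ± 0.17), COL9A2 (0.87 ± 0.18) and RTL1 (0.93 ± 0.19) rose. Of 19 midbrain, hindbrain and hypothalamic genes 7 fell, such as EN2 (-4.06 ± 0.57) and LMX1A (-3.84 ± 0.63), and 13 adjusted over the list alone (camera adjusted p = 5.54e-09, and adjusted p = 0.0124 with an estimated correlation). Of 20 mesenchymal and matrix genes 2 fell over all genes, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 2e-06, but adjusted p = 0.246 with an estimated correlation). In all 20 rose and 143 fell in H9. The total was 109 with the split as a covariate, 84 within the libraries with gut transcripts, 72 in DESeq2 and 3 when only these libraries were fitted, and 47, 48, 73 and 100 without library 12, 14, 11 or 15.

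In H1, 20 genes rose and 2 fell between acute and chronic dopamine. BTBD11 (2.09 ± 0.24, adjusted p = 0.00044), DCT (1.88 ± 0.28), SSTR1, a somatostatin receptor (1.21 ± 0.2), ID1 (1.5 ± 0.25) and TAC1 (1.71 ± 0.3) rose, while KIAA0408 (-8.77 ± 1.44) and a gene without a symbol fell. Of 9 neural crest and melanocyte genes 3 rose, including TYRP1 (2.67 ± 0.47) and PMEL (2.48 ± 0.46), and 5 adjusted over the list alone (camera adjusted p = 2.05e-14, and adjusted p = 0.003 with an estimated correlation). The GABAergic list (adjusted p = 0.0366 with an estimated correlation) and the oligodendrocyte list (0.0316) passed as well, with 1 gene each over all genes and 7 and 3 adjusted over the list alone. The count of 22 was 4 with the split as a covariate, 1 within the libraries with gut transcripts and 8 in DESeq2, and without library 1, 2, 3, 4 or 6 it was 1, 4, 2, 3 and 6.

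Averaged over lines 7 genes rose and 17 fell between acute and chronic dopamine. BTBD11 (1.03 ± 0.14, adjusted p = 0.00702), NKX2-2 (1.78 ± 0.28), CD27-AS1 (0.83 ± 0.15), ARHGAP36 (2.35 ± 0.44) and ID1 (0.92 ± 0.17) rose. ARHGAP36 had 0 to 1 counts in H1 acute and 2 to 8 in H1 chronic libraries, so its averaged fold is uncertain. In H9, where ARHGAP36 is expressed, the log2 fold change is 1. NKX2-2 was at 0.171 ± 0.163 CPM in H1 acute and 1.3 ± 0.405 in H1 chronic libraries, so its averaged fold is uncertain too. In H9 NKX2-2 was at 46.2 ± 6.96 and 70.7 ± 17. FREM1 (-1.27 ± 0.18), PCDHGB1 (-1.22 ± 0.18), ZIC2 (-2.95 ± 0.45) and PRDM8 (-1.02 ± 0.16) fell. PCDHGB1 shares exons with its gene cluster, so its reads are uncertain. Of 18 dorsal forebrain genes NEUROD1 (-1.47 ± 0.26), NEUROG2 (-2.31 ± 0.42), NEUROD2 (-2.99 ± 0.54) and BHLHE22 (-1.69 ± 0.31) fell. Adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 1.1e-15, but adjusted p = 0.0777 with an estimated correlation). The larger part of these averaged falls lay in H9, where levels were low. NEUROD2 was at 1.42 ± 1.05 CPM in H9 acute and 0.023 ± 0.0398 in H9 chronic libraries, against 451 ± 71.2 and 348 ± 49.2 in H1. BHLHE22 was at 6.49 ± 2 and 0.74 ± 0.298 in H9, and 236 ± 50.4 and 197 ± 49.1 in H1. ZIC2 was at 5.55 ± 2.5 and 0.0902 ± 0.0413 in H9, and 58.3 ± 11.3 and 55.6 ± 7.31 in H1. The count of 24 was 15 with the split as a covariate and 17 within the libraries with gut transcripts. It was 12, 7, 9, 11 and 13 without library 1, 3, 10, 12 or 14, and 42 without library 11. HMOX1 was at 0.54 ± 0.18, NQO1 at 0.45 ± 0.13, TH at 1.37 ± 0.45 and PPP1R1B at -1.22 ± 0.34, and none passed. The averaged folds of TH and PPP1R1B are uncertain, since each was low in 1 line. TH was at 0.0395 ± 0.0346 CPM in H1 acute and 0.183 ± 0.088 in H1 chronic libraries, against 14.9 ± 1.28 and 22.7 ± 6.59 in H9. PPP1R1B was at 1.39 ± 0.915 and 0.319 ± 0.382 in H9, and 27.8 ± 8.65 and 22.1 ± 3.88 in H1. Of 28 NRF2 and antioxidant genes 25 had positive values, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.0074, but adjusted p = 0.472 with an estimated correlation). Of 19 dopamine receptor, synthesis and transport genes 17 had positive values, 0 passed over all genes and 1 was lower adjusted over the list alone (0.0202, but adjusted p = 0.279 with an estimated correlation).

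The acute and chronic effects share their control libraries. Across genes, which are not independent replicates, the line-averaged log2 fold changes had a Pearson correlation of 0.551, and 20 simulations with no effect gave 0.567. The covariance was 0.082 against 0.047 simulated, a difference of 0.035. No call was shared, where independent lists would share 0, since there was no acute call. Pairs that share no library had correlations of -0.127 (acute in H1, chronic in H9) and 0.048 (acute in H9, chronic in H1), against -0.004 ± 0.016 and 0 ± 0.016 (SD) simulated. The simulations drew genes independently, so their spread leaves out correlation between genes, and neither value is read as an effect. Within H1 the correlation was 0.698 against 0.609 simulated and the covariance 0.267 against 0.126. Within H9 the correlation, 0.375, was below the simulated 0.499, and the covariance was 0.088 against 0.062. The 3 acute calls in H1 were also chronic calls, against 0.04 for independent lists, and part of that excess may come from the shared controls.

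The authors' deposited tables of their own comparisons list 55 acute and 213 chronic genes. The sign of the fold column opposed that of the log2 column for all 55 and 213. Among tested genes the fold column of the authors' deposited tables had the direction of treated over control in H9 for 39 of 39 acute and 201 of 201 chronic genes, with a median absolute difference of 0.01 in log2 fold change, and in H1 for 15 of 39 and 60 of 201. The values are thus those of H9 alone, with log2 given as control over treated. By that column of the authors' deposited results, 30 acute genes were higher and 25 lower, and 6 and 207 chronic ones. In edgeR 0 of the 39 acute and 84 of the 201 chronic genes passed in H9, and 0 and 8 in the line average.

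Among the largest folds in the authors' deposited acute table were those of HOXB6 (196.94, chromosome 17 from 48595736 to 48604992), HOXB8 (183.83), HOXA10 (98.26) and HSD11B1 (-81.32). In H9 acute libraries 13, 14 and 15 HOXB6 had 8, 1 and 237 counts, HOXB8 10, 5 and 392, and HOXA10 55, 3 and 261. H9 controls had 0 to 3 counts of each, so these HOX folds rest mostly on library 15. In edgeR HOXB8 had a log2 fold change of 7.5 (adjusted p = 0.369) in H9. HSD11B1 had 57 and 55 counts in H9 controls 17 and 18, 0 in control 16 and 0 to 1 in the H9 acute libraries. Its fold thus rests on controls 17 and 18, which hold blood transcripts. In the authors' deposited chronic table the largest folds were those of HBB (-749.26), S100A9 (-692.8), HBA2 (-385.38), COL3A1 (-183.32) and COL1A1 (-78.23). HBB, S100A9 and HBA2 are blood transcripts of H9 controls 17 and 18, and had adjusted p = 0.152, 0.218 and 0.127 in edgeR, while COL3A1 and COL1A1 passed (0.0125 and 0.0136). Against controls, the fall of COL1A1 comes from the same 2 controls, with 2427 and 2397 counts in them, 17 in control 16 and 16 to 20 in the chronic libraries. The H9 acute libraries 13, 14 and 15 had 765, 334 and 61 COL1A1 counts.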

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

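The test of the line difference was planned before the data were examined, while the tests of globin, of the gut transcripts of library 9, of held-out genes, of the acute median and of library 15 were chosen after the result was seen.

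A difference between the lines in the chronic effect was found for 303 genes in edgeR. The H9 minus H1 difference in log2 fold change was -3.22 for WLS, -4.81 for SLITRK6, -3.39 for PDE5A, -4.21 for WNT5A and -2.88 for BTBD11, and 2.51 for OSTN, 1.85 for SMIM11B, 1.3 for ME3, 7.93 for KIAA0408 and 2.15 for CHRM5. Of 80 splits of the libraries 1, the real one, gave as many genes, and the highest other gave 114. The splits cover only the grouping of these libraries. Differences between cultures are not tested, since the labels do not say whether the 3 libraries of a group came from separate cultures. The count was 68 without library 8, 146 without library 1, 173 without library 17 and 194 without library 7. WLS, SLITRK6, PDE5A, WNT5A, BTBD11 and OSTN passed without each library in turn. SMIM11B missed the threshold without library 8, KIAA0408 without library 1, 2, 3, 7, 9, 11 or 17 (0.27 without 7), ME3 without 1, 2, 7, 8, 12 or 17, and CHRM5 without 1, 2, 8, 10, 12, 16, 17 or 18.

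GABAergic genes were higher in H1 chronic libraries than in H1 controls, with a median log2 fold change of 2.51 over 28 genes. With the blood or gut split as a covariate the median was 2.24 with 13 members passing, and without library 9 it was 2.52 with 14, which argues against either as the whole cause. Within the 13 libraries with gut transcripts it was 1.94 with 2 members passing, where the H1 controls are libraries 7 and 9. H1 acute libraries, with 1 hour of dopamine, had a median of 1.54, or 0.615 of the chronic one. Both medians use the same H1 controls, so part of that share may come from them, and no value without an effect was computed. Differences between organoids or batches that need no week of dopamine could hold part of the change, and an effect of dopamine stays open too.

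Blood transcripts were found in 5 libraries and gut transcripts in the other 13. Embryonic and fetal globin made up 10 counts against 4312 of the adult chains in the 5 libraries, a ratio of 0.00232, which argues against blood cells formed from the stem cells. Library 9 held 22 gut transcripts, where the share in the other 12 would give 0.199, and the others held 62 to 101, which argues against a fixed share of each library's RNA. Held-out blood genes averaged 8.1 CPM in the blood set and 0.375 in the gut set, and held-out gut genes 3.2 CPM in the gut set and 0.636 in the blood set, the larger share being 0.166, so whether a whole foreign transcriptome is present stays open. Carry-over from other samples during preparation or sequencing may be the source, which no label can test.

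HOX genes lead the authors' deposited acute table. Over its 5 tested HOX genes the H9 median log2 fold change was 4.85, and 2.36 without library 15. Their summed counts were 89, 48 and 1433 in acute libraries 13, 14 and 15, and 11, 13 and 21 in controls. Whether library 15 alone is the cause cannot be told apart from a smaller rise in all 3 acute libraries, since the median falls between the bounds set for the test. No biological explanation was tested.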

How the results depend on the processing

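The fits of the split by blood and gut genes, of 13 and 12 libraries and without libraries 9 and 11 were chosen after the data were seen, and the other alternatives before the data were examined. No paired analysis was possible because each library has its own number. Results that kept direction and side of the threshold in edgeR and its alternatives are given as counts. For 178 gene values and 46 list values, leaving out 1 library kept 1460 and 561 values, weakened 174 and 63, strengthened 8 and 0 and turned 56 and 0. Other settings kept 2115 and 271, weakened 402 and 131, strengthened 19 and 0 and turned 76 and 6. Among the 13 libraries with gut transcripts H9 control has 1 library, which is assumed to vary like the other groups. The depth of library 9 limits every H1 control comparison of low genes. In this part a mean is over lines, a count is of genes past the threshold, and the cause was not tested for any change below.

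With DESeq2 size factors, counts were 48 for chronic mean, 1 for acute H1 and 8 for chronic-acute H1. Without a low-count filter, counts were 74 for acute mean, 386 for chronic mean, 189 for chronic-acute mean, 116 for acute H1, 117 for acute H9, 535 for chronic H1, 438 for chronic H9, 107 for chronic-acute H1, 467 for chronic-acute H9, 95 for acute line difference and 679 for chronic line difference. Against a fold of 1.2, counts were 37 for chronic mean, 13 for chronic-acute mean, 1 for acute H1, 59 for chronic H9, 3 for chronic-acute H1 and 80 for chronic-acute H9. With only the libraries compared, counts were 0 for acute H1, 370 for chronic H1, 4 for chronic H9, 8 for chronic-acute H1 and 3 for chronic-acute H9. A surrogate variable, which mainly sets library 9 apart, gave 217 for chronic mean, 77 for chronic-acute mean, 1 for acute H9, 488 for chronic H1, 57 for chronic H9, 57 for chronic-acute H1, 108 for chronic-acute H9 and 559 for chronic line difference. DESeq2 gave 63 for acute H1, 2 for acute H9, 59 for chronic H9, 8 for chronic-acute H1, 72 for chronic-acute H9, 1 for acute line difference and 166 for chronic line difference. Limma on log2(TPM + 1) gave 2 for chronic mean, 1 for chronic-acute mean, 0 for acute H1, 1 for acute H9, 46 for chronic H1, 4 for chronic H9, 3 for chronic-acute H1, 17 for chronic-acute H9, 24 for chronic line difference and 5899 for H9 against H1. Limma on log2(TPM + 0.1) gave 1 for chronic mean, 0 for chronic-acute mean, 0 for acute H1, 1 for acute H9, 33 for chronic H1, 1 for chronic H9, 0 for chronic-acute H1, 2 for chronic-acute H9, 4 for chronic line difference and 4636 for H9 against H1. The additive model gave 0 for chronic mean and 0 for chronic-acute mean. Treatment alone gave 0 for chronic mean, 0 for chronic-acute mean and 0 for chronic genes of the authors' table. An estimated correlation gave 0 for acute lists, 1 for chronic lists, 0 for chronic-acute lists and 0 for H9 against H1 lists. Fry gave 0 for acute lists, 2 for chronic lists, 0 for chronic-acute lists and 29 for H9 against H1 lists. The blood or gut split as a covariate gave 21 for chronic mean, 15 for chronic-acute mean, 5 for acute H1, 29 for chronic H9 and 4 for chronic-acute H1. Among the 13 libraries with gut transcripts, counts were 3 for chronic mean, 0 for acute H1, 6 for acute H9, 23 for chronic H1, 7 for chronic H9, 1 for chronic-acute H1, 84 for chronic-acute H9, 1 for acute line difference, 24 for chronic line difference and 6 for chronic lists. Among 12 of these, without library 9, counts were 1 for acute mean, 4 for chronic mean, 0 for acute H1, 1 for acute H9, 12 for chronic H1, 6 for chronic H9, 1 for chronic-acute H1, 92 for chronic-acute H9, 2 for acute line difference and 15 for chronic line difference. Leaving out libraries 9 and 11, counts were 203 for chronic mean, 62 for chronic-acute mean, 561 for chronic H1, 55 for chronic H9, 53 for chronic-acute H1 and 628 for chronic line difference.

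The genes named here did not pass in the comparison unless the report says so, and values are log2 fold changes. With DESeq2 size factors, the sign turned for FOS (0), NR4A1 (0) in chronic mean and FOS (-0.03) in chronic H9. A surrogate variable turned the sign of DRD4 (0.11) in acute mean, DRD4 (-0.16) in chronic-acute mean and DRD1 (0.17) in chronic H9. DESeq2 turned the sign of DRD5 (-0.39) in acute mean, DRD5 (-0.04), FOS (0) in chronic mean, DRD4 (-0.03) in chronic-acute mean, DRD5 (-0.75) in acute H1, DRD5 (-0.56) in chronic H1 and FOS (-0.03) in chronic H9. Limma on log2(TPM + 1) turned the sign of FOS (0.31), NR4A1 (0.37), NQO1 (0.36) in acute mean, PLAT (0.04), TXNIP (0.24) in chronic mean, NR4A1 (0.92), TH (0) in acute H1, DRD5 (0.01) in acute H9, NR4A1 (0.86) in chronic H1 and FOS (-0.05) in chronic H9. Limma on log2(TPM + 0.1) turned the sign of FOS (0.82), NR4A1 (0.87), NQO1 (0.89) in acute mean, PLAT (0.43), TXNIP (0.24) in chronic mean, DRD4 (-0.04) in chronic-acute mean, NR4A1 (1.96), TH (0.05) in acute H1, DRD5 (0.02) in acute H9, NR4A1 (1.89) in chronic H1, FOS (-0.05) in chronic H9 and OSTN (-0.09), ME3 (-0.07) in chronic line difference. The additive model turned the sign of HMOX1 (-0.01) in acute mean. Treatment alone turned the sign of DRD1 (-0.1), DRD2 (-0.2), DRD5 (-0.28), HMOX1 (-0.3) in acute mean and FOS (-0.07), TXNIP (0.04) in chronic mean. The blood or gut split as a covariate turned the sign of DRD4 (-0.34) in chronic-acute mean, DRD4 (-0.08), DRD5 (0.05) in acute H9 and DRD4 (-0.37) in chronic H9. Among the 13 libraries with gut transcripts, the sign turned for HMOX1 (-0.01) in acute mean, DRD4 (-0.14) in chronic-acute mean, FOS (-0.16), NR4A1 (0.07), PPP1R1B (0.07) in acute H1, DRD1 (0.11), DRD5 (0.2), TXNIP (-0.08) in acute H9, FOS (-0.06) in chronic H1 and DRD1 (0.05) in chronic H9. Among the 13 libraries with gut transcripts, the direction turned for the mesenchymal and extracellular matrix list in the acute comparison (adjusted p = 0.00437), the nuclear-encoded respiratory chain list in the chronic comparison (adjusted p = 0.578) and the mesenchymal and extracellular matrix list in the chronic comparison (adjusted p = 0.693). Among 12 of these, without library 9, the sign turned for DRD4 (0.15), HMOX1 (-0.01) in acute mean, DRD4 (-0.16) in chronic-acute mean, FOS (-0.17), NR4A1 (0.02), NQO1 (-0.01), PPP1R1B (0.1) in acute H1, DRD1 (0.1), DRD5 (0.19), TXNIP (-0.08) in acute H9, FOS (-0.09) in chronic H1 and DRD1 (0.02) in chronic H9. Among 12 of these, without library 9, the direction turned for the mesenchymal and extracellular matrix list in the acute comparison (adjusted p = 1.4e-07), the nuclear-encoded respiratory chain list in the chronic comparison (adjusted p = 0.772) and the mesenchymal and extracellular matrix list in the chronic comparison (adjusted p = 0.0514). Leaving out libraries 9 and 11, the sign turned for DRD4 (0.07) in acute mean, FOS (-0.02), NR4A1 (-0.06) in chronic mean, DRD4 (-0.38) in chronic-acute mean and DRD1 (0.28), DRD4 (-0.38), FOS (-0.03) in chronic H9. The correlation of the acute and chronic effects was -0.127 for acute in H1 with chronic in H9, and 0.048 for acute in H9 with chronic in H1.

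Leaving out each library in turn, counts ranged over 6 to 145 for chronic mean, 7 to 42 for chronic-acute mean, 46 to 280 for chronic H1, 1 to 15 for chronic-acute H1, 68 to 377 for chronic line difference, 7 to 14 for chronic-acute lists, 0 to 4 for acute mean, 0 to 16 for acute H1, 0 to 4 for acute line difference, 7 to 18 for acute lists, 13 to 178 for chronic H9, 47 to 145 for chronic-acute H9 and 0 to 31 for acute H9. Values ranged as follows. For chronic mean they were DRD4 -2.29 to 0.12, FOS -0.04 to 0.11 and NR4A1 -0.06 to 0.09. For chronic-acute mean they were DRD1 -0.03 to 0.36, DRD4 -0.39 to 0.38 and DRD5 -0.95 to 1.62. For chronic H1 they were DRD2 -0.12 to 0.84, DRD5 0 to 3.2 and FOS -0.09 to 0.08. For acute mean they were DRD2 -0.04 to 0.45, DRD4 -2.33 to 0.08, DRD5 -0.03 to 1.5, HMOX1 -0.11 to 0.2, NQO1 -0.23 to 0.11 and TH -0.82 to 1.17. For acute H1 they were DRD2 0 to 0.97, DRD5 0 to 3.06, FOS -0.09 to 0.1, NR4A1 -0.17 to 0.1, NQO1 -0.01 to 0.66, PPP1R1B -0.45 to 0.01 and TH -1.5 to 2.48. For chronic H9 they were DRD1 -0.52 to 0.27, DRD4 -0.39 to 0.92 and FOS -0.08 to 0.21. For acute H9 they were DRD1 -0.22 to 0.1, DRD2 -0.21 to 0.01, DRD4 -0.24 to 0.72, DRD5 -0.19 to 0.13 and TXNIP -0.19 to 0.24.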

Other observations

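The list tests within lines and the genes of this part were chosen after the data were seen, while the splits of the libraries were planned.

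In H1 chronic libraries some genes of the retina list rose. SIX3, an eye and forebrain factor, went from 3.48 ± 0.0234 CPM (n = 2) to 21.1 ± 2.79 (n = 3, log2 fold change 2.6 ± 0.43), RPE65, a visual cycle enzyme, rose by 1.9 ± 0.31, and OTX2 by 2.04 ± 0.35. These were 3 of 6 retina genes in edgeR, with 3 adjusted over the list alone (camera adjusted p = 0.000551, but adjusted p = 0.0818 with an estimated correlation). SST, which encodes somatostatin, went from 0.142 ± 0.0485 to 3.09 ± 1.6 CPM (4.4 ± 0.8). SLC7A11, a cystine transporter and NRF2 target, rose by 1.35 ± 0.31 (adjusted p = 0.0284), 1 of 28 genes of its list, with 2 adjusted over the list alone (camera adjusted p = 0.304).

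In H9 chronic libraries LOX, which crosslinks collagen, fell from 16.7 ± 5.6 to 5.98 ± 0.791 CPM (n = 3 each, -1.48 ± 0.26), and PLOD2, a collagen hydroxylase, by -0.77 ± 0.14. These were 2 of 34 hypoxia response genes in edgeR, with 4 adjusted over the list alone (camera adjusted p = 5.76e-07, but adjusted p = 0.324 with an estimated correlation). Collagen genes fell in the same comparison, such as COL3A1 from 42.6 ± 37.5 to 0.223 ± 0.168 CPM. Whether the fall of LOX and PLOD2 is separate from that of the mesenchymal genes was not tested. FOXJ1, a factor of ciliated cells, fell from 13.9 ± 2.38 to 4.09 ± 1.08 CPM (-1.76 ± 0.36), and CFAP126 by -1.65 ± 0.32, 2 of 14 choroid plexus and ciliated genes, with 5 adjusted over the list alone (1.07e-06, but adjusted p = 0.192 with an estimated correlation).

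Splits of the libraries were compared with each count of called genes. For acute dopamine averaged over lines the real count was 0 (edgeR, 345 higher and 152 lower at an unadjusted p under 0.05, 0 in DESeq2), so 80 of 80 splits necessarily gave as many and nothing about chance is tested. The highest other gave 21. For the line difference of the acute effect the real count was also 0 (edgeR, 138 and 500 at an unadjusted p under 0.05, 1 in DESeq2), so 80 of 80 splits test nothing there either, and the highest other gave 61. For chronic dopamine averaged over lines 6 of 80 splits gave as many as the real 74, and the highest other, 303, swaps the labels of 1 line and so is the test of the line difference, a structure of the samples. Chance cannot be excluded for that count of 74, which was 6 without library 8, 145 without library 11, and 49, 47 and 42 without library 1, 12 or 17. For chronic against acute 3 of 80 gave as many as the real 24, a share under the 0.05 set in advance, but an earlier draw lay over it. The highest other, 80, swaps the labels of H1 alone, a structure of the samples. Chance is therefore not taken as excluded for that count. For H9 against H1 1 of 80 gave as many as the real 11896, and the highest other gave 7313, which reflects the structure of the 2 lines. Differences between cultures are not tested by any of these splits.

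Within lines the 10 splits of 3 against 3 are too few for a share under 0.05. The real count and the highest other were 3 and 13 for acute dopamine in H1 (2 of 10 as large), 0 and 21 in H9 (10 of 10; edgeR, 166 higher and 227 lower at an unadjusted p under 0.05, 2 in DESeq2), 244 and 0 for chronic dopamine in H1 (1 of 10) and 99 and 6 in H9 (1 of 10). For chronic against acute they were 22 and 10 in H1 (1 of 10) and 163 and 0 in H9 (1 of 10).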
